A study of Oryza sativa with 12 samples.

How the data were processed

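The series holds 12 libraries of polysome-bound mRNA from rice leaf, 2 cultivars by control or drought with 3 libraries per group, from TRIzol-extracted polysomal RNA. Groups and replicate numbers came from the sample labels, and no library was reassigned. Total RNA was not used here, so translational efficiency was not analysed here.

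The submitters' processing notes name HISAT2 2.1.0, StringTie 1.3.4 and DESeq2 2.11.38, with no role or order. The StringTie gene tables of the authors give each gene's coverage, a signal unit that is the mean read depth per base and is not scaled between libraries. The deposited FPKM values scale that depth by the library's reads, and the deposited TPM values sum to a fixed total over all annotated genes of a library, rRNA and organelle genes included. Counts of reads were not used here, so the count-based test named in the plan for that case did not apply, and read depth is known only as the relative index of coverage divided by FPKM. The genome build and the annotation release were not stated in the sources used here.

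The choices of test, filter, threshold, named genes and list names were made before the data were examined. The planned test was limma 3.58.1 (R 4.3.3) with an intensity trend on log2(TPM + 1), in 1 fit with a mean for each of the 4 groups and no replicate block. Genes with a mean of at least 1 TPM over the 12 libraries were tested (18631 genes), with Benjamini-Hochberg adjustment and a call at adjusted p < 0.05. Every p-value of a gene is from limma's moderated t test, two-sided. The SE of a gene's log2 difference is the moderated one, pooled over the groups of the fit and drawn towards the trend over genes. It can be smaller than the spread of the libraries compared would give. Gene lists with at least 5 tested genes were tested with camera (limma), which compares the members with all other genes, at a preset correlation of 0.01, adjusted over the lists of a comparison. Members called were counted with adjustment over all genes and adjusted over the list alone. Overlap was tested by Fisher's exact test. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

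The list names were fixed in advance by product text, but the tables and references at hand gave gene symbols and no product text. Members were therefore matched by symbol patterns, written after the tables were opened and before any difference between groups was computed. Symbols were present for 10843 genes, 9826 of them at nuclear loci. Of the lists 29 were tested in the planned test. Seed storage proteins and root markers had too few tested genes there, root markers passed below the other genes in IR64 with nuclear scaling of 10 libraries (5 genes, adjusted p = 0.00297, and adjusted p = 0.278 with an estimated correlation), and plastid ribosomal proteins matched no symbol. Genes were classed as nuclear loci (37849), nuclear rRNA (262), organelle rRNA (13), other nuclear noncoding (645), chloroplast (117) and mitochondrion (92). Genes were named by a rule fixed in advance: among called genes with every library of 1 group above every library of the other and an informative name, the 10 largest in each direction, up to 4 called members of each list, and the 10 largest differences between cultivars, with the 5 smallest p given as not passing where fewer than 5 were called. Where a symbol belonged to more than 1 locus the locus is given. Related genes such as those of the RbcS and RAB16 families may share reads, and the tables give no count of shared reads.

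The other settings fixed in advance were a pseudocount of 0.1, no filter, a filter at 5 TPM, FPKM, median-of-ratios scaling, quantile normalization, fits of only the groups compared, library weights, a replicate block, a fold threshold, an estimated correlation in camera and leaving out each library. Settings added after the data were seen were TPM rescaled to the same total over nuclear loci (26192 genes tested), 10 libraries in deposited TPM (19206 tested), both together (22812 tested) and leaving out each library of the nuclear-scaled fits. The 2 libraries left out for the 10 had under 10% of TPM on nuclear loci. The level of log2 difference at which genes are detected was tested on simulated data with the planned test: of genes given a change of 2, 4 or 8 log2 units, 2.99, 38.8 and 98.5% were called in APO and 2.99, 52.2 and 93.9% in IR64, with 4.12% of 97 and 4.81% of 104 calls false. A simulated list given a shift passed in camera in both comparisons, and 1 without a shift did not. The simulated noise was normal and drawn separately for each gene, with no shift common to a library and no correlation between genes. The false shares and list results of the simulation therefore do not carry over to the real libraries, whose rRNA shares differ. Changes in both directions were added to the log2 values with no floor at 0. Simulated falls could thus pass below 0, which log2(TPM + 1) cannot, so the shares of changes called do not carry over either.

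Cultivar-typical genes were chosen for each library from the other deep libraries (lowest level of at least 8 nuclear-scaled TPM in 1 cultivar and at least 8 times the highest of the other plus 0.5), and counted as detected above 1. Replicate numbers were checked for pairing by correlating the deviations of same-numbered libraries from their group means.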

Results

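Polysome-bound mRNA was sequenced from leaves of rice (Oryza sativa) of 2 cultivars, APO, which the series title calls tolerant, and IR64, which it calls susceptible. Each cultivar was grown as control or under 50% drought, with 3 libraries in each of the 4 groups and 12 libraries in all. The sources used here do not say whether the 3 libraries of a group came from separate plants. The p-values of genes (limma) therefore measure only a spread between libraries, which may be technical. That spread is pooled over the 4 groups and also draws on the other genes. The p-values of gene lists at the preset correlation, of overlaps and of the binomial test take genes as the units. They do not measure replication between libraries. Total RNA was not used here, so a difference in polysomal mRNA was not separated from a difference in total mRNA. The genome build was not stated, and gene coordinates are those of the deposited tables.

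Ribosomal RNA took very different shares of the libraries. Total rRNA held 52.34 ± 44.83% of TPM in APO control, 61.37 ± 51.72% in APO drought, 6.63 ± 8.61% in IR64 control and 67.21 ± 16.18% in IR64 drought (mean ± SD, n = 3). The share of TPM on nuclear gene loci was 32.97, 77.47 and 5.04% in APO control 1, 2 and 3, and 13.27 and 76.41% in APO drought 2 and 3. In the library labelled APO drought 1 it was 1.21%. The IR64 libraries held 59.88, 79.83 and 83.35% in control and 31.74, 38.65 and 12.26% in drought. Read counts were not used here, and a relative index of depth (coverage divided by FPKM) ran from 0.61 in IR64 drought 3 to 7.34 in IR64 control 2. Nuclear loci above 0 numbered 9976 in the library labelled APO drought 1 and 15357 to 31980 in the others. Because a larger rRNA share lowers the TPM of every other gene, each comparison is given in deposited TPM over 12 libraries, the planned test. It is given again with TPM rescaled over nuclear loci and without the 2 libraries below 10% nuclear TPM (APO control 3 and the library labelled APO drought 1). This form, the nuclear-scaled test of 10 libraries, was chosen after the data were seen and leaves 2 APO libraries on each side.

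**Figure D1:**
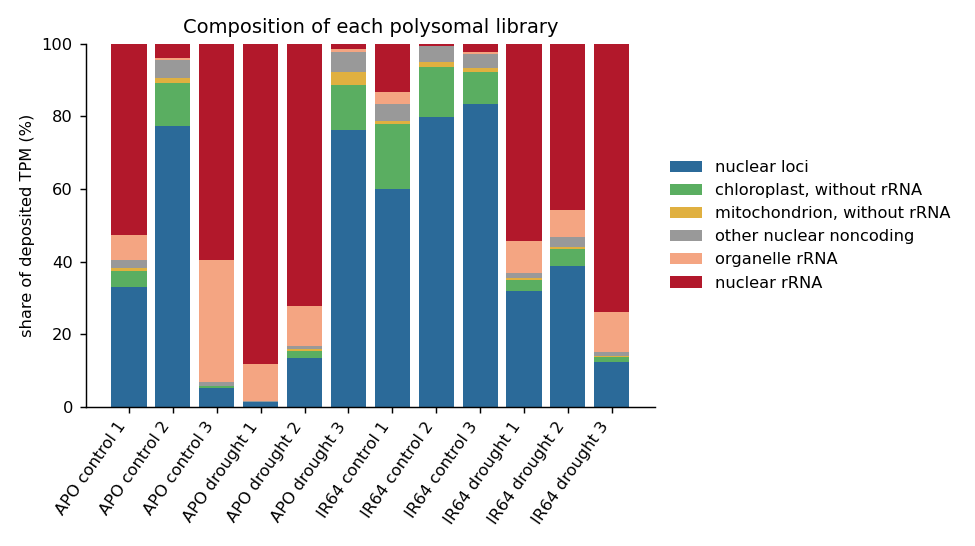
Stacked bars show the percent of deposited TPM (y axis) on each class of gene in each of the 12 libraries (x axis, by group and replicate). Nuclear loci held from 1.21% in the library labelled APO drought 1 to 83.35% in IR64 control 3.

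Genes typical of 1 cultivar were used to compare each library with its label. They were chosen from the other libraries as genes at 8 or more nuclear-scaled TPM throughout 1 cultivar and at least 8 times higher than in the other. In the library labelled APO drought 1, 0 of 14 APO-typical genes lay above 1 nuclear-scaled TPM, while 11 of 16 IR64-typical genes did, with a median of 21.3. The other 11 libraries were nearer to the cultivar of their labels. Among them APO control 3, with 14 of 14 APO-typical genes, also had 9 of 16 IR64-typical genes above 1 (median 2.21), IR64 control 1 had 7 of 17 APO-typical genes (median 0.491), APO control 2 had 5 of 20 IR64-typical genes (median 0.15), and the rest had 0 to 3 genes of the other cultivar. Within IR64 control, libraries 1 and 2 resembled each other (Spearman 0.96) more than either resembled library 3 (0.87 and 0.87), which was closer to APO control 2 (0.94) and to IR64 drought 1 and 2 (0.91 and 0.90). CCA1, a morning gene of the circadian clock, stood at 636 and 953 nuclear-scaled TPM in IR64 control 1 and 2 and at 1.91 in IR64 control 3. OsRcaII, a Rubisco activase, stood at 42500 and 56300 against 278. In APO, CCA1 stood at 3.44, 1.63 and 6.01 in control 1, 2 and 3, at 33.7 in the library labelled APO drought 1, and at 82.6 and 55.5 in APO drought 2 and 3. All libraries stayed in the groups of their labels.

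**Figure D2:**
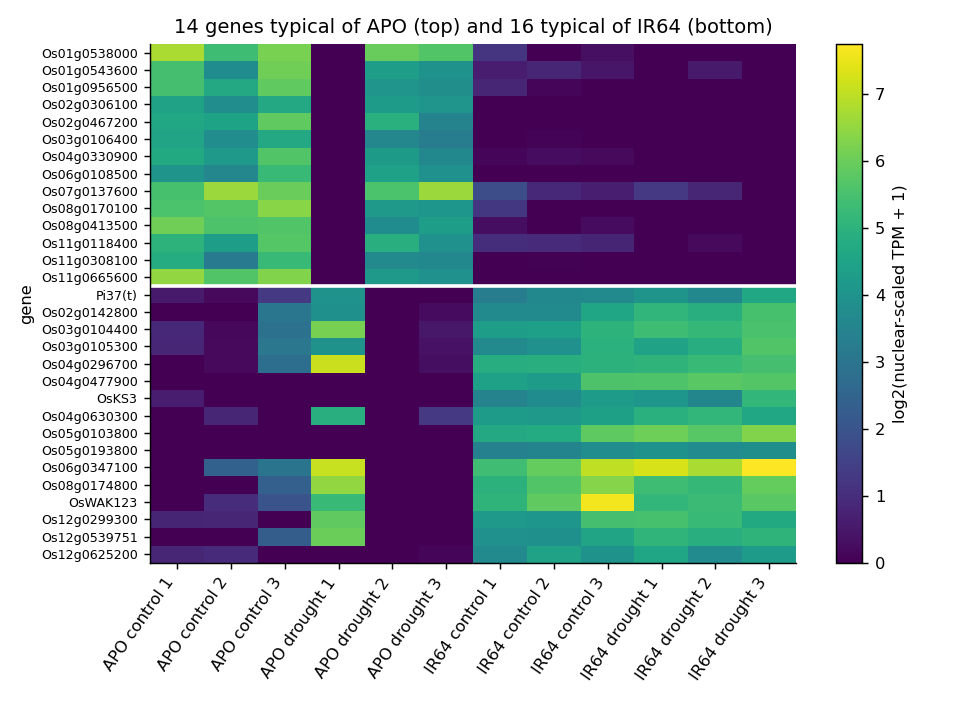
The heat map shows log2(nuclear-scaled TPM + 1) of 14 APO-typical and 16 IR64-typical genes (rows) in the 12 libraries (columns). The library labelled APO drought 1 had 0 of the 14 APO-typical genes above 1 and 11 of the 16 IR64-typical genes.

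The first question was how drought changed polysomal mRNA in APO. The largest rises were in late embryogenesis abundant (LEA) proteins and dehydrins, which protect dehydrating cells. Rab16A (Os11g0454300, chromosome 11, 15342877 to 15343671) rose by 7.0 ± 1.73 log2 units (SE; n = 3 and 3; adjusted p = 0.0196), from a nuclear-scaled mean of 27.7 ± 3.23 to 33500 ± 16200 TPM (SD, n = 2 and 2, with APO control 3 at 120 and the library labelled APO drought 1 at 2640). Of the 27 LEA genes measured, 24 were higher in drought, 13 rose and 0 fell (21 up and 1 down adjusted over the list alone), with a median of 3.75. Among them OsLEA3-1 (Os05g0542500, chromosome 5, 26927607 to 26928882) rose by 6.52 ± 1.66 and RAB16B by 6.52 ± 1.59. The lipid transfer proteins OsLTP2.5 (6.27 ± 1.37) and OsLTPd6 (5.66 ± 1.40) rose too, as did OsGS1 (Os03g0712800, chromosome 3, 28822424 to 28826321; 4.71 ± 0.87, adjusted p = 0.000254). OsGS1 reached 802 ± 135 nuclear-scaled TPM in drought from 1.79 ± 0.392, and was 0 in the library labelled APO drought 1.

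Of the genes that fell in APO, the largest change was in the jacalin-related lectin OsJAC1 (Os12g0247700, chromosome 12, 8239432 to 8241147; -7.18 ± 1.27, adjusted p = 0.000145). OsLOX11, a lipoxygenase (-6.69 ± 1.51), the peroxidase POX22.3 (-5.28 ± 1.24) and HSR201 (-4.02 ± 0.74) also fell. Genes of the photosynthetic light reactions had a median of -3.34 over 30 members, of which 0 fell and 1, OsPsbR2, rose (3.46 ± 0.93; 1 up and 8 down adjusted over the list alone). Of these 30, 20 fell and 1 rose in the nuclear-scaled test of 10 libraries (21 and 1 adjusted over the list alone; list median -3.40). PsbY, a small subunit of photosystem II (-6.25 ± 0.51), and RbcS5, a small subunit of Rubisco (Os12g0291400, chromosome 12, 11277247 to 11278306; -6.98 ± 0.53), fell there. RbcS5 went from 3910 ± 590 to 31.6 ± 15.3 nuclear-scaled TPM (SD, n = 2 and 2), but stood at 1000 in the library labelled APO drought 1. OsGDCH of photorespiration (-8.49 ± 0.68), the ribosomal protein gene RPL5 (-4.53 ± 0.41) and the chlorophyll synthesis gene YGL1 (-5.06 ± 0.81) fell as well. Rises in the same test included HSP70 (Os03g0277300; 8.03 ± 0.54), the asparagine synthetase ASN1 (7.58 ± 0.71), P5CS2 of proline synthesis (6.36 ± 0.67) and OSNCED3 of abscisic acid synthesis (5.28 ± 0.89).

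The planned test in APO (limma) called 86 of 18631 genes, 56 up and 30 down, with 1595 at unadjusted p < 0.05 and a median of -0.75 over all genes. With nuclear scaling and 10 libraries 3285 of 22812 genes were called (1551 up, 1734 down; median -0.24), among them all 86. Nuclear scaling of all 12 libraries called 793 (247 up, 546 down), with 49 of the 86 among them (19 of the 56 rises and all 30 falls). Of 29 lists 17 passed (camera), 10 above and 7 below the other genes. Besides LEA proteins (adjusted p = 1.39e-53, and 0.153 with an estimated correlation) these were pathogenesis-related proteins, cuticle and lipid transfer, heat shock, osmolyte metabolism, senescence, sugar transport, abscisic acid, NAC factors and mitochondrion-encoded genes above (7.26e-07 to 0.0403). Of these, heat shock (-0.05), abscisic acid (-0.39), NAC factors (-0.35) and mitochondrion-encoded genes (-0.55) had medians below 0. Below were light reactions (3.48e-06), chloroplast-encoded genes (1.81e-05), Calvin cycle (0.00327), cytosolic ribosomal proteins (0.00378; median -1.50, 0 of 80 higher), WRKY factors, chlorophyll synthesis and photorespiration (0.0153 to 0.0371). With an estimated correlation no list passed in either test (lowest adjusted p = 0.153 with an estimated correlation in the planned test and 0.105 in the nuclear-scaled test of 10 libraries). Lists that did not pass had adjusted p from 0.0961 to 0.854: antioxidant enzymes, aquaporins, cell wall, ERF and DREB factors, glutathione S-transferases, guard cell markers, histones, jasmonate, nitrogen, secondary wall, shoot meristem and translation factors. The direction of the list median depended on the scaling or on the libraries kept for abscisic acid, antioxidant enzymes, cell wall, cuticle, ERF and DREB factors, glutathione S-transferases, guard cell markers, heat shock, mitochondrion-encoded genes, NAC factors, nitrogen, secondary wall and shoot meristem. The planned count was 6 without APO control 1, 14 without APO control 2, 567 without APO control 3, 502 without the library labelled APO drought 1, 5 without APO drought 2, 16, 9 and 57 without IR64 control 1, 2 and 3, and 45 and 57 without IR64 drought 1 and 2. The nuclear-scaled count was 1022, 1153 and 1217 without APO control 1, APO control 2 and APO drought 2. Here and in the later comparisons, leaving an APO library out of the 10 leaves 1 library in its group, so the error of such a count comes from the other groups. Fitting only the APO groups gave 0 calls in the planned test (514 at unadjusted p < 0.05).

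**Figure D3:**
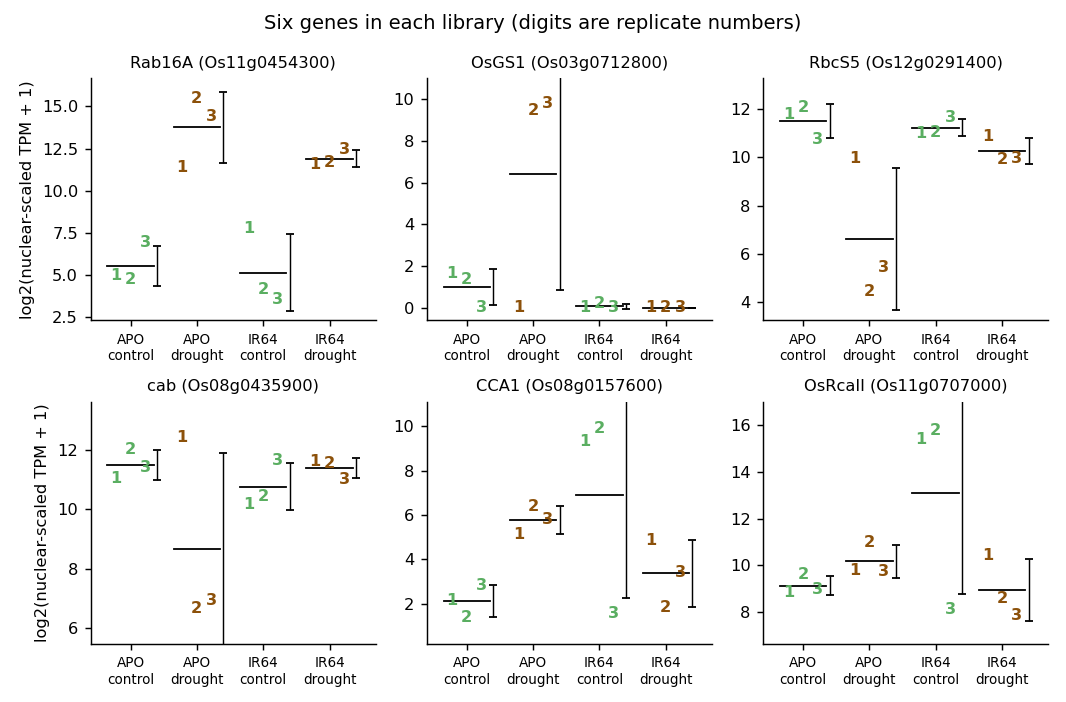
Levels of 6 genes on the y axis as log2(nuclear-scaled TPM + 1) in the 4 groups (x axis); digits are the replicate numbers of single libraries, lines the group means and bars the SD. Rab16A was higher in drought in both cultivars, while RbcS5 fell to a mean of 31.6 TPM in APO drought 2 and 3, with the library labelled APO drought 1 at 1000.

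The next question was how drought changed polysomal mRNA in IR64. LEA genes were again the group that moved furthest upward: 22 of 27 were higher, with a median of 2.39, and 1 rose, OsLEA3 (4.35 ± 1.2; n = 3 and 3; 8 up and 0 down adjusted over the list alone). OsLTPd6 (4.77 ± 1.40) and OsLTP2.5 (4.49 ± 1.37) rose as in APO. The 10 largest rises were all rRNA genes (5.62 to 6.52). Among genes that fell, HD3A (Os06g0157700, chromosome 6, 2940004 to 2942452), which encodes the florigen of rice, fell by 6.09 ± 1.10 (adjusted p = 9.41e-05), from 120 ± 82.5 to 0 nuclear-scaled TPM (SD, n = 3 and 3). The boron transporter BOR2 fell by 5.52 ± 0.89 and OsRcaII by 5.69 ± 1.74. Both were high in IR64 control 1 and 2 and low in IR64 control 3. BOR2 stood at 178 and 345 TPM against 1.2, and OsRcaII at 42500 and 56300 nuclear-scaled TPM against 278. Of 285 nuclear loci called lower, 239 were higher in IR64 control 1 and 2 than in each of the other 10 libraries. Aquaporins, the water channels, had 4 of 22 members falling and 0 rising (7 and 0 adjusted over the list alone; list median -1.93), with OsPIP1 (Os02g0823100) at -5.10 ± 1.52. With nuclear scaling and 10 libraries 1 of 24 aquaporins fell and 1 rose (6 and 1 adjusted over the list alone), with a list median of -0.98. Of 30 nitrogen genes 4 fell and 0 rose (7 and 0 adjusted over the list alone), namely AMT1 (-4.44 ± 1.24), the nitrate reductase genes OsNIA2 (-4.43 ± 1.02) and OsNIA1 (-3.56 ± 0.99), and the nitrate transporter NRT2.4 (-3.75 ± 0.74). With nuclear scaling of 12 libraries 0 of 39 nitrogen genes were called in either direction, and the list median was -0.11 against -1.18.

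With nuclear scaling and 10 libraries most IR64 calls were rises (255 up, 70 down), against 1 up and 1 down with nuclear scaling of 12 libraries. Both tests hold the same IR64 libraries, so the IR64 fold change of a gene is the same. They differ in the APO libraries left out, which had entered the shared error and the choice of genes tested. With 12 libraries 0 of 33 LEA genes were called (15 up and 0 down adjusted over the list alone). With 10 libraries LEA genes rose in 16 of 31 cases and fell in 0 (18 and 0 adjusted over the list alone, list median 2.67). Rab16A rose by 6.76 ± 0.89 (adjusted p = 0.0107, limma, n = 3 and 3) and OsLEA3-1 by 5.30 ± 0.75. OsPP2C51, a protein phosphatase 2C gene (4.47 ± 0.66), OsDREB1C (Os06g0127100; 4.13 ± 0.66) and HSP70 (Os03g0277300; 2.68 ± 0.44) rose. HD3A (-6.52 ± 0.72), the proline dehydrogenase OsProDH (-4.06 ± 0.71), OsNCED1 (Os02g0704000; -3.85 ± 0.66) and OsPIP1 (Os02g0823100; -3.84 ± 0.67) passed there as well. BOR2 (-5.70 ± 1.57, adjusted p = 0.111) and OsRcaII (-4.13 ± 1.65, 0.219) did not pass, BOR2 at about its planned size and with a larger error. Cytosolic ribosomal proteins had a median of 0.70 with 71 of 81 higher and 0 called. As a list they passed above the other genes (camera, adjusted p = 3.42e-05), but not with an estimated correlation (0.278 or more). Light reactions had a median of -0.11 with 0 called (list adjusted p = 0.0831).

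The planned test in IR64 (limma) called 398 genes, 110 up and 288 down, with 2011 at unadjusted p < 0.05 and a median of -0.94 over all genes. The nuclear-scaled test of 10 libraries called 325 genes (255 up, 70 down; median 0.16). Of the 398 planned calls only 291 lie at nuclear loci and were tested there, 285 falls and 6 rises, the other rises being mostly of rRNA genes. Of these 291, 50 were called again, 44 falls and all 6 rises. Nuclear scaling of all 12 libraries left 2 calls, 1 of them among the 291, and a median of 0.04. Of 29 lists 8 passed the planned test (camera). LEA proteins (adjusted p = 4.4e-26, and 0.866 with an estimated correlation), cuticle, ERF and DREB factors and secondary wall genes (0.00168 to 0.00261) lay above the other genes, the last 3 with medians below 0 (-0.57, -0.28 and -0.31). Aquaporins, guard cell markers, nitrogen and Calvin cycle genes lay below (0.00168 to 0.021). In the nuclear-scaled test of 10 libraries 14 of 28 lists passed at the preset correlation (camera), 7 above and 7 below the other genes. With an estimated correlation no list passed in the planned test (camera, adjusted p from 0.866 to 0.991). None passed with an estimated correlation in the nuclear-scaled test of 10 libraries either (lowest adjusted p = 0.278). The other 21 lists had adjusted p from 0.0582 to 0.955. Nuclear scaling turned the list median from below to above 0 for abscisic acid (-0.51 to 0.73), antioxidant enzymes (-1.39 to 0.02), ribosomal proteins (-0.79 to 0.70), cuticle, ERF and DREB factors, secondary wall, pathogenesis-related proteins, senescence, sugar transport, translation factors, osmolyte metabolism and NAC factors. The planned count was 137, 638, 633, 177 and 844 without APO control 1, APO control 3, the library labelled APO drought 1, APO drought 2 and APO drought 3, 37 and 14 without IR64 control 1 and 2, and 73, 34 and 47 without IR64 drought 1, 2 and 3. The nuclear-scaled count of 10 libraries was 154, 155, 139 and 84 without APO control 1, APO control 2, APO drought 2 and APO drought 3, 137, 62 and 3912 without IR64 control 1, 2 and 3, and 64 and 84 without IR64 drought 2 and 3.

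**Figure D4:**
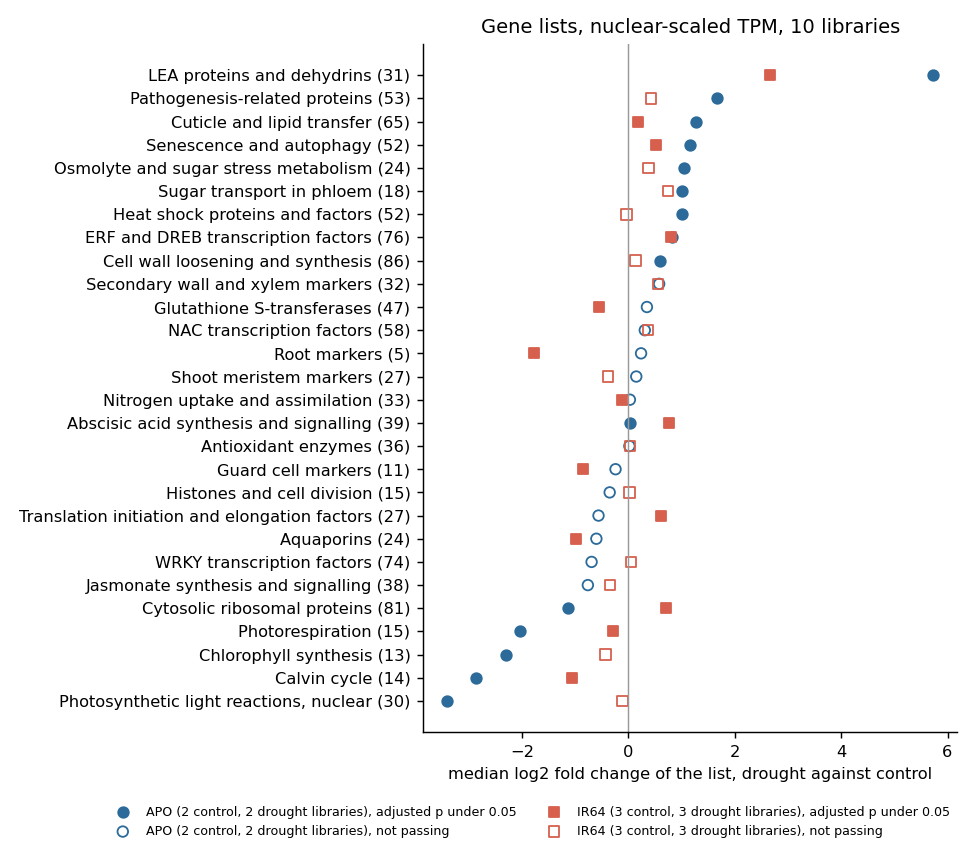
Median log2 fold change of drought against control (x axis) of each gene list (y axis, number of genes in brackets) in the nuclear-scaled test of 10 libraries; circles are APO (2 and 2 libraries), squares IR64 (3 and 3), and filled marks passed at adjusted p < 0.05 with the preset correlation, none with an estimated one. LEA proteins lay at 5.73 in APO and 2.67 in IR64, light reactions at -3.40 and -0.11; list medians near 0 changed sign with scaling.

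Genes called in both cultivars were few in the planned test. OsLTPd6, OsLTP2.5 and OsLEA3 rose in both (3 genes, 0.33 if independent, Fisher's exact p = 0.00442), and Os09g0275400 fell in both (1 gene, 0.46 if independent, p = 0.374). With nuclear scaling and 10 libraries 198 genes rose in both (17.34 if independent, odds ratio 54.4, Fisher's exact p = 3.87e-181), among them Rab16A, OsLEA3-1, ASN1 and HSP70 (Os03g0277300). In that test 43 fell in both (5.32 if independent, Fisher's exact p = 1.11e-30). The comparisons of both cultivars shared 1 estimate of the spread for each gene, so a gene with a small spread is more readily called in both. Fisher's exact test takes no account of this or of correlation between genes. The planned overlap of rises was 0 without APO control 1, APO control 2, APO drought 2 or any 1 IR64 library, 1 without APO drought 3, 5 without APO control 3 and 10 without the library labelled APO drought 1. The planned overlap of falls was 0 without the same 9 libraries, 11, 32 and 3 without the other 3 in that order. The nuclear-scaled overlap of rises was 96, 97, 78 and 47 without APO control 1, APO control 2, APO drought 2 and APO drought 3, 114, 55 and 566 without IR64 control 1, 2 and 3, and 37 and 61 without IR64 drought 2 and 3. That of falls was 14, 8, 11, 14, 9, 5, 228, 11 and 13 in the same order.

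A further question was whether the drought effect differed between the cultivars. In the planned test 10 genes passed, all with a higher (APO minus IR64) effect: OsSIG5 (8.24 ± 1.71; n = 3 per group), a sigma factor gene, OsPPT4 (6.0), BOR2 (5.41), the vitamin E synthesis gene OsVTE3 (5.38), OsMyb1R (5.13), the sugar transporter OsSWEET2b (4.79) and Os01g0666600, Os02g0137700, Os01g0642100 and Os08g0187900 (5.19 to 6.81). Each was high in IR64 control 1 and 2 and low in IR64 control 3. OsMyb1R and Os01g0642100 were higher still in APO drought 3 (39.2 and 90.8 TPM). In the nuclear-scaled test of 10 libraries the largest differences included Lhca6 of the photosystem I antenna (-8.32 ± 1.61), OsGS1 (8.23 ± 0.76), OsGDCH (-7.75 ± 0.88), PsbY (-6.69 ± 0.66) and RbcS5 (-6.00 ± 0.69). Of 30 light-reaction genes 15 had a lower effect in APO and 0 a higher one (20 and 1 adjusted over the list alone), and of 31 LEA genes 11 had a higher effect and 0 a lower one (16 and 1 adjusted over the list alone). Ribosomal protein genes had 5 of 81 lower and 0 higher (42 and 0 adjusted over the list alone), with RPL5 at -4.79 ± 0.53.

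For this difference the planned test (limma) had 920 genes at unadjusted p < 0.05 beside its 10 calls, all upward. The nuclear-scaled test of 10 libraries called 1183 genes (351 up, 832 down), with 3 of the 10 among them, while nuclear scaling of all 12 libraries called 0 (2789 at unadjusted p < 0.05, limma). The median over all genes was 0.24 in the planned test and -0.33 in the nuclear-scaled test of 10 libraries. Of 29 lists 14 passed the planned test (camera): LEA proteins (adjusted p = 0.000735, and 0.971 or more with an estimated correlation for every list), heat shock, pathogenesis-related proteins, guard cell markers, aquaporins, glutathione S-transferases, mitochondrion-encoded genes, nitrogen, osmolyte metabolism and sugar transport above (0.000797 to 0.0277). Chloroplast-encoded genes, ribosomal proteins, light reactions and secondary wall genes lay below (0.000593 to 0.0274). Nuclear scaling of 12 libraries put the medians of glutathione S-transferases (-0.05), nitrogen (-0.40) and sugar transport (-0.33) below 0. Secondary wall genes lay above the other genes, not passing, in the nuclear-scaled test of 10 libraries (adjusted p = 0.957; median -0.09), and the other 15 lists had adjusted p from 0.0934 to 0.922. The planned count was 0 without APO control 1, APO drought 2, IR64 control 1, IR64 control 2, IR64 drought 2 or IR64 drought 3, 1 without IR64 drought 1, 3 without APO drought 3, 24 without APO control 3, 83 without IR64 control 3 and 368 without the library labelled APO drought 1. The nuclear-scaled count of 10 libraries was 15, 47, 143 and 2139 without APO control 1, APO control 2, APO drought 2 and APO drought 3, 218, 425 and 4633 without IR64 control 1, 2 and 3, and 319, 631 and 704 without IR64 drought 1, 2 and 3.

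The cultivars were then compared in control plants. OsJAC1 was higher in APO by 8.23 ± 1.27 log2 units (adjusted p = 1.68e-06; n = 3 and 3), HSR201 by 4.2 ± 0.74 and OsTPP7, a trehalose phosphate phosphatase, by 3.54 ± 0.88. OsTPP7 stood at 75 nuclear-scaled TPM in APO and 0.509 in IR64. Lower in APO were the wall-associated kinase gene OsWAK123 (-5.40 ± 1.12), CCA1 (-5.62 ± 1.25) and BOR2 (-5.40), of which CCA1 and BOR2 were high in IR64 control 1 and 2 and near the APO levels in IR64 control 3. Among 30 nitrogen genes 3 were lower, OsNIA2 (-4.63), AMT1 (-4.51) and NRT2.4 (-3.56), and 0 higher (6 and 0 adjusted over the list alone). Among 22 aquaporins 2 were lower and 0 higher (8 and 0 adjusted over the list alone). With nuclear scaling of 12 libraries 0 genes of either list were called. Adjusted over the list alone, 5 aquaporins were lower there and 0 higher, and 0 nitrogen genes passed in either direction. With nuclear scaling and 10 libraries OsJAC1 (9.75 ± 0.67), OsTPP7 (5.79 ± 0.63) and OsWAK123 (-5.68 ± 0.71) kept their differences, OsPR1b was higher in APO (4.95 ± 0.75), and CCA1 (-5.14 ± 1.97, adjusted p = 0.422) and BOR2 (-5.43 ± 1.76, 0.358) did not pass, with differences near the planned ones and larger errors.

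Of 18631 genes 234 differed in control plants (limma; 53 higher and 181 lower in APO; 1605 at unadjusted p < 0.05; median -0.85). The nuclear-scaled test of 10 libraries called 138 (104 and 34; median 0.32), with 75 of the 234 among them, and nuclear scaling of 12 libraries called 29, with 26 of the 234. Of 29 lists 7 passed (camera): aquaporins, nitrogen, guard cell markers, sugar transport and light reactions below (adjusted p = 0.00278 to 0.0448), and WRKY factors and cell wall genes above (0.0118 and 0.0448, with medians of -0.36 and -0.32). With an estimated correlation none passed (adjusted p = 0.973 with an estimated correlation), and the other 22 had adjusted p from 0.0776 to 0.869. Nuclear scaling of 12 libraries put the medians of guard cell markers (0.33), nitrogen (0.16), sugar transport (0.08), WRKY factors (1.15) and cell wall genes (1.15) above 0. Both cultivars were read against 1 reference, so a difference between them can come from mapping. The planned count was 22 without APO control 1, 499 without the library labelled APO drought 1, 150 without APO drought 2, 652 without APO drought 3, and 44 and 24 without IR64 control 1 and 2. The nuclear-scaled count of 10 libraries was 0 and 72 without APO control 1 and 2, and 39, 32 and 2894 without IR64 control 1, 2 and 3.

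In drought plants OsGS1 differed most between the cultivars, higher in APO by 5.33 ± 0.87 log2 units (moderated SE, adjusted p = 1.38e-05, limma, n = 3 and 3). OsGS1 stood at 706 and 897 nuclear-scaled TPM in APO drought 2 and 3. It was 0 in the library labelled APO drought 1 and in each IR64 drought library. OsDT11 (3.61 ± 0.69), OsEnS-40 (3.41 ± 0.68), OsC3H10 (3.16 ± 0.69) and the metallothionein gene OsMT2d (3.98 ± 0.93) were higher in APO as well, as were Os04g0480700, Os06g0163450, Os06g0473800 and Os12g0450300. No gene passed as lower, ONAC129 coming closest among named genes (-3.06, adjusted p = 0.158). Light-reaction genes had a median of -3.26 with 0 called (0 up and 5 down adjusted over the list alone). In the nuclear-scaled test of 10 libraries 20 of 30 were lower in APO and 1 higher, with PsbY at -5.86 and RbcS5 at -5.31 ± 0.49, while 18 of 31 LEA genes and 20 of 53 pathogenesis-related genes, among them OsPR1b (6.70), were higher.

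Of 18631 genes 9 differed in drought plants, all higher in APO (limma; 842 at unadjusted p < 0.05; median -0.61). The nuclear-scaled test of 10 libraries called 2815 (1292 higher, 1523 lower; median -0.05), with all 9 among them, and nuclear scaling of 12 libraries called 46, with 1 of the 9. Of 29 lists 10 passed (camera). LEA proteins, pathogenesis-related proteins, mitochondrion-encoded genes and heat shock genes lay above (adjusted p = 1.48e-11 to 0.00392), of which mitochondrion-encoded (-0.07) and heat shock genes (-0.44) had medians below 0, both above 0 with 10 libraries (1.24 and 0.84). Light reactions, chloroplast-encoded genes, ribosomal proteins, chlorophyll synthesis, Calvin cycle and secondary wall genes lay below (1.24e-11 to 0.00408), with none passing with an estimated correlation (adjusted p = 0.989 or more with an estimated correlation). Secondary wall genes turned to a higher median, not passing, in the nuclear-scaled test of 10 libraries (adjusted p = 0.9), and the other 19 lists had adjusted p from 0.0545 to 0.957. The planned count was 5 without APO control 1, APO drought 2, IR64 control 1 or IR64 control 2, 19 without APO control 3, 218 without the library labelled APO drought 1, 2 without APO drought 3, and 1 without IR64 drought 1 or 2. The nuclear-scaled count of 10 libraries was 691, 4381 and 1479 without APO drought 2, IR64 control 3 and IR64 drought 1.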

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

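The tests of the explanations and the splits in this part were chosen after the results were seen. The genes and lists of the last paragraph are from the planned test of the difference between the cultivars' drought effects.

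The library labelled APO drought 1 carried 0 of 14 APO-typical genes above 1 nuclear-scaled TPM and 68.8% of 16 IR64-typical genes, at a median of 21.3, which would suggest a mislabelled sample. Low depth alone was excluded, since other genes of similar level were detected in 73.4% of cases and 0 of 14 then has p = 8.97e-09 (exact binomial test). A weaker response of an APO plant alone gives no account of the IR64-typical genes at a median of 21.3. The cultivar-typical genes do not measure the drought response, so such a response beside carried-over IR64 reads was not excluded. A swap within the series was excluded, since 0 libraries labelled IR64 carried the APO pattern. Reads carried over from IR64 libraries cannot be told apart from a mislabelled sample (0 APO-typical genes above 1). Genotyping of the reads would settle it.

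IR64 control 1 and 2 differed from IR64 control 3 by 8.06 log2 units in CCA1, with the evening genes OsPRR1 (-1.03), OsELF3.2 (-3.11) and GI (-1.06) in the opposite direction, so a hypothesis is that they were harvested at another time of day; LHY (Os04g0583900), a morning gene by its symbol, did not follow CCA1 (-0.88, at 3.09 and 1.49 against 4.88 TPM). A wrong cultivar label was excluded, since IR64 control 3 had 100% of the IR64-typical genes, while an exchange of treatment labels was not tested (Rab16A stood at 10.6 there and at 3050, 3270 and 5650 in IR64 drought). The rRNA share was excluded, since that of IR64 control 3 (2.31%) lay between those of the other 2 (13.3 and 0.44%). Of 285 nuclear loci called lower in IR64 drought, 210 (73.7%) had IR64 control 3 nearer to the drought mean than to the other controls. The planned falls in IR64 and genes such as CCA1 and BOR2 in the comparison of control plants rest on the same libraries. The 10 differences between cultivars rest on them in part. For OsMyb1R the drought effect was 2.73 in APO and -2.4 in IR64, and for Os01g0642100 3.17 and -2.95, none of these passing alone. All these results may therefore reflect harvest time as much as drought or cultivar.

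The median of all genes below 0 in deposited TPM may come from the rRNA share in IR64. It moved there from -0.94 over 18631 genes to 0.04 over 26192 nuclear loci once TPM was rescaled over nuclear loci. The genes tested changed as well, in both cultivars, so the moves were not traced to rescaling alone. In APO the median stayed at -0.63 after rescaling (-0.88 to -0.36 with any 1 library left out). With rescaling and without the 2 libraries lowest in nuclear TPM it was -0.24. The effect of the rRNA share on the scaling was therefore excluded as the whole cause there, but not as a part of it. Rescaling does not restore genes missed at a low nuclear share, so such losses were not excluded. In the library labelled APO drought 1, 999 of 3753 genes at similar levels in both cultivars were listed at 0.

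Splitting the libraries of each comparison in all other ways gave counts as large as the real one, the real one included, as follows. For the difference between cultivars 20 of 100 splits did (real value 10, highest other 14868), so a grouping by chance was not excluded. The splits of the other comparisons are too few (10) for a share under 0.05: 3 in APO (real value 86, highest other 14716), 1 in IR64 (398, highest other 46), 1 in control plants (234, highest other 81) and 3 in drought plants (9, highest other 274). The APO split with 14716 calls set APO control 1, APO control 2 and APO drought 3 against the other 3. The first 3 held 32.97, 77.47 and 76.41% of TPM on nuclear loci, and the others 5.04, 1.21 and 13.27%. The APO splits thus also follow library composition and do not measure chance alone.

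The planned test of the difference between cultivars marked these values. The genes were OsSIG5 (8.24), Os01g0666600 (6.81), Os02g0137700 (6.73), Os01g0642100 (6.12), OsPPT4 (6.0), BOR2 (5.41), OsVTE3 (5.38), Os08g0187900 (5.19), OsMyb1R (5.13) and OsSWEET2b (4.79). Lists with a higher median effect in APO were LEA proteins (1.83), guard cell markers (1.71), osmolyte metabolism (1.37), pathogenesis-related proteins (1.31), sugar transport (1.31), aquaporins (1.2), heat shock (1.09), glutathione S-transferases (1.08), mitochondrion-encoded genes (0.94) and nitrogen (0.88). Lists with a lower one were light reactions (-1.44), chloroplast-encoded genes (-0.86), secondary wall (-0.86) and cytosolic ribosomal proteins (-0.67). With an estimated correlation none of these lists passed (adjusted p = 0.971 or more with an estimated correlation), and nuclear scaling of 12 libraries put glutathione S-transferases (-0.05), nitrogen (-0.40) and sugar transport (-0.33) below 0.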

How the results depend on the processing

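The settings with nuclear scaling or 10 libraries were chosen after the data were seen, the others before the data were examined, and the cause of each change was not tested. The sizes of the counts depended on the scaling, on the filter and on which libraries were kept. Rises of LEA genes in both cultivars held their direction in every scaling, whereas list directions near 0 and most counts did not.

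Counts follow in the order APO drought, IR64 drought, difference between cultivars, control plants, drought plants, against 86, 398, 10, 234 and 9 in the planned test. A pseudocount of 0.1 gave 10, 66, 0, 48 and 2 calls (628 at unadjusted p < 0.05 for the 0, limma). No filter gave 2, 3, 0, 8 and 1 (1472), and a mean TPM of at least 5 gave 25, 154, 1, 43 and 1. FPKM gave 92, 376, 19, 230 and 9. Median-of-ratios scaling gave 971, 1, 0, 54 and 36 (2142 at unadjusted p < 0.05, limma), and quantile normalization 1264, 6, 0, 128 and 36 (2765). Fitting only the groups compared gave 0, 495, 10, 536 and 0 (514 and 543 at unadjusted p < 0.05 for the 0 calls in APO and in drought plants, limma). Library weights gave 18267, 7946, 12176, 11749 and 13903, but these rest on 2 libraries, since the weights did not converge (43681.16 for APO control 1 and 23012.12 for APO drought 2, others at most 1.57). Nuclear scaling gave 793, 2, 0, 29 and 46 (2789), 10 libraries 1260, 1253, 521, 402 and 518, and both together 3285, 325, 1183, 138 and 2815. A threshold of 1 on the absolute log2 fold change left the planned counts as they were.

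Leaving out any 1 library gave, lowest and highest over deposited TPM, nuclear scaling and nuclear scaling with 10 libraries, 5 and 4803 calls in APO, 0 and 3912 in IR64, 0 and 4633 for the difference, 0 and 2894 in control plants and 0 and 4381 in drought plants. Without an APO library the 10 leave 1 library in its group, whose spread is then taken from the other groups. In deposited TPM alone the ranges were 5 to 567, 14 to 844, 0 to 368, 22 to 652 and 1 to 218. The overlap of rises ran from 0 to 10 and of falls from 0 to 32 in deposited TPM.

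The overlap of rises and of falls between cultivars (3 and 1 in the planned test) was 0 and 0 with a pseudocount of 0.1, with no filter and with only the groups compared. It was 1 and 0 with a mean TPM of at least 5, 2 and 1 with FPKM, 0 and 1 with median-of-ratios scaling, 1 and 4 with quantile normalization, 579 and 4994 with library weights, 1 and 1 with nuclear scaling, 25 and 115 with 10 libraries and 198 and 43 with both.

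Same-numbered libraries showed no pairing: the correlations of their deviations had a median of -0.09 (-0.47 to 0.33), and 2 of 18 lay above 0.1. A replicate block gave 16, 80, 0, 119 and 5 calls (726 at unadjusted p < 0.05 for the 0, limma) and an overlap of 0 and 0.

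Among lists that passed in the planned test or in nuclear scaling with 10 libraries, directions turned between these for secondary wall genes in the difference between cultivars (adjusted p = 0.957, and 0.977 with an estimated correlation) and in drought plants (0.9 and 0.946), and for LEA proteins in control plants (Down, adjusted p = 0.032, and 0.587 with an estimated correlation). Other lists that turned passed in neither.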

Other observations

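All tests named in this part were chosen after the results were seen. In the nuclear-scaled test of 10 libraries, 16 of 76 ERF and DREB genes rose and 1 fell in APO (list adjusted p = 0.00207, and 0.384 with an estimated correlation), and 3 rose and 0 fell in IR64. In deposited TPM of the same 10 libraries, 2 of 59 rose and 8 fell in APO (list adjusted p = 0.405, camera). The values below are again from the nuclear-scaled test. Sugar transport genes rose in 6 of 18 cases and fell in 1 in APO, with OsSWEET15 at 6.41 ± 0.69, and pathogenesis-related genes rose in 19 of 53 and fell in 2, with OsPR4c at 6.29 ± 0.59. SGR, a gene of chlorophyll breakdown, rose in APO by 3.57 ± 0.72, and WRKY45 fell (-4.93 ± 0.95). One LEA gene, OsLEA11, was lower in APO drought in that test (-3.78, adjusted p = 0.0457).

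Mitochondrial transcripts per 100 nuclear TPM were 2.13 ± 0.47 in APO control, 3.63 ± 1.03 in APO drought, 1.57 ± 0.12 in IR64 control and 1.70 ± 0.26 in IR64 drought (SD, n = 3). Chloroplast transcripts were 13.1 ± 2.31, 14.37 ± 2.92, 19.3 ± 9.79 and 11.37 ± 1.40. Principal component 1 of the 10 libraries held 34.6% of the variance and set APO drought 2 and 3 (220.15 and 132.45) apart. APO control 3 had 377 nuclear loci at 1 nuclear-scaled TPM or more that lay below 0.1 in the other 11 libraries, against 0 to 101 such loci in each of the others. CCA1 stood at 3.44, 1.63 and 6.01 nuclear-scaled TPM in APO control 1, 2 and 3 and at 82.6 and 55.5 in APO drought 2 and 3, with 33.7 in the library labelled APO drought 1. The evening gene OsELF3.2 stood at 97.4, 62.2 and 65.3 in APO control, at 40.5 and 33.3 in APO drought 2 and 3, and at 178 in the library labelled APO drought 1. OsPRR1 stood at 136, 72.2 and 149 against 44.1 and 68.2, with 190 in the library labelled APO drought 1, while GI (1130, 756 and 597 against 486 and 809, with 1060 in that library) did not separate the groups. LHY (Os04g0583900) stood at 9.59, 4.77 and 50.4 in APO control, at 158 and 187 in APO drought 2 and 3, and at 0 in the library labelled APO drought 1. Harvest time was not tested for APO, so it stays open there too.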
